A study of Rattus norvegicus with 18 samples.

How the data were processed

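Gene expression was measured in rats on 18 arrays, 9 from subcutaneous abdominal fat and 9 from hypothalamus. In each tissue 3 arrays came from Pair-Fed animals, 3 from animals labelled RYGB-Success and 3 from animals labelled RYGB-Fail. RYGB is Roux-en-Y gastric bypass, an operation that makes a small stomach pouch and joins it to a lower part of the small intestine. Per the labels, Success stands for animals that were losing weight after the operation and Fail for animals that were regaining it. Groups and replicate numbers were taken from the sample titles.

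Total RNA was extracted with a Qiagen RNeasy kit and amplified and biotin-labelled with the NuGEN WT-Ovation system, per the labels' protocols. The deposited values are linear signal intensities, 1 per probe set, made with MAS5 and GCOS per the submitters' processing notes. Versions and settings of these tools were not given in the sources used here. In every deposited array column the mean intensity after trimming the lowest and highest 2% was 499.98 to within rounding, so the authors' values had already been scaled to a common mean. This scaling equalises the trimmed mean and not the median, and a few very bright probe sets can shift all others on an array. MAS5 signals near the lower end scatter widely on a log scale. Detection calls were not used here.

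The table held 31099 probe sets. Of these, 20826 had a single gene symbol in the platform annotation, 436 had several, 9780 had none and 57 were array controls, which were left out of all tests. Gene identifiers of 20764 probe sets matched a RefSeq gene table of the GRCr8 assembly, and 0 symbols needed updating. No gene was named from a probe set with several symbols. One probe set stood for each gene in the gene list tests and among the fixed anchor genes, the one with the highest mean signal in the tissue.

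Values were taken as log2 of the deposited signal, with no pseudocount. In each tissue the upper 60% of probe sets by mean log2 signal were tested, which left 18625 probe sets with a mean signal of at least 88.9 in fat and 52.7 in hypothalamus, covering 10145 and 10438 named genes. Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) over all 9 arrays of a tissue, so that the 3 groups shared 1 estimate of the spread. The 3 pairwise comparisons were tested 2-sided, and an F test asked whether any group differed. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The difference between tissues was tested as an interaction over the 15531 probe sets that passed the filter in both. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for annotation and plots.

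Before the data were examined, 42 gene lists were fixed, 25 of pathways and 17 of cell type or brain region markers, with 856 genes of which 748 were on the array. Lists could share genes, so their calls are not independent. Every adipocyte marker is also in the adipokine list. The matrix and fibroblast lists share Col1a1, Col1a2, Col3a1, Dcn and Lum. The macrophage and microglia lists share C1qa, C1qb, Tyrobp, Aif1, Csf1r and Itgam. Lists with at least 5 measured members were tested with camera at its preset correlation of 0.01, which made 30 lists in fat and 29 in hypothalamus. The same lists were also tested with camera at an estimated correlation and with fry, whose directional p asks whether a list's genes move one way on balance and does not compare them with other genes. Counts of members that passed after adjustment over the list alone are given beside those over all probe sets.

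The genes named in each comparison follow a rule that was fixed at the same time. It takes the 6 largest increases and the 6 largest decreases among probe sets that passed, had 1 symbol and had groups whose arrays did not overlap. Free places were filled by the lowest unadjusted p among probe sets with non-overlapping groups and a fold of at least 1.5. It adds up to 4 members with the lowest p of each list described, and anchor genes of fat and hypothalamus biology given whatever their result.

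The limma and camera steps were tested on simulated data with the spread of the real arrays before use. For RYGB-Success against Pair-Fed in fat, the limma step run over 18625 probe sets recovered 1.47% of changes of 1 log2, 30.3% of changes of 2 and 80.3% of changes of 4. In hypothalamus the shares were 39.7%, 80.3% and 100%. Of the simulated calls, 3 of 77 in fat and 11 of 157 in hypothalamus were unchanged probe sets. A list shifted by 0.5 log2 was found in both tissues, with 0 unshifted lists called. The simulated genes varied independently of one another. The simulation therefore does not show how often camera calls unshifted lists when the genes of a list are correlated.

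Alternatives planned before the data were examined were a pseudocount of 10% of the tissue's mean signal, no filter, a filter keeping the upper 40%, quantile normalization, centring each array on its median, array weights, a robust variance model, the replicate number as a block, fits of only the 2 groups compared, 1 probe set or the mean of all probe sets per gene, and leaving out each array in turn. Covariates for array brightness, muscle marker level and epithelium marker level in fat, and for the 3' to 5' signal ratio of the beta-actin controls in hypothalamus, were added after the data had been seen. So was a check that set every array's value to no less than the lowest mean signal kept by the filter, for named genes whose dimmer group lay under it and for called lists.

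Precision was limited by the number of arrays, 3 per group. The submitters describe the replicates as biological.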

Results

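The arrays matched their tissue labels. In the 9 fat arrays the signal of Adipoq, the adipocyte hormone adiponectin, ran from 17271 to 60117, against 86.0 to 410 in hypothalamus. Snap25, a protein of nerve terminals, ran from 13279 to 25290 in hypothalamus and from 52.0 to 1089 in fat. Median signals were 91.1 to 127 on the hypothalamus arrays. In fat they were 98.2 to 200 on 8 arrays and 288 on the third RYGB-Fail array. That array had a median correlation of 0.727 with the other fat arrays, where the others had 0.801 to 0.900, and it received the lowest array weight, 0.175. Its beta-actin controls had a 3' to 5' signal ratio of 2.46, against 12 to 24.3 on the other fat arrays, and on hypothalamus arrays this ratio ran from 6.65 to 179. Among hypothalamus arrays the third RYGB-Success array had the lowest median correlation, 0.904 against 0.929 to 0.959 for the others, the lowest array weight, 0.331, and the lowest 3' to 5' ratios of beta-actin, 6.65, and GAPDH, 1.58. Changes below are differences of log2 signal ± SE from the limma fit, with 3 arrays per group, and levels are mean log2 signal ± SD. For mean changes of gene lists, ± is the SE from the arrays' list means, pooled over the 3 groups. Where the lower group's mean lay under the filter's lowest mean signal, 88.9 in fat and 52.7 in hypothalamus, a fold is also given as at least the value with every array at no less than that signal, which is not a measured detection limit.

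**Figure D1:**
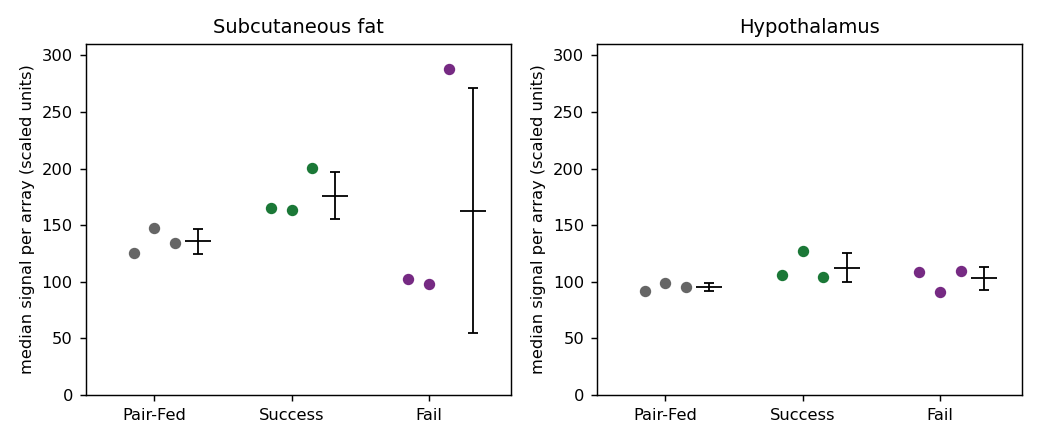
Median signal of each array in scaled units, by tissue and group, with points for single arrays and black bars for the mean ± SD of 3 arrays. The third RYGB-Fail fat array lies at 288, above the 98.2 to 200 of the other fat arrays.

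Success against Pair-Fed fat asked how fat of animals losing weight after bypass differed from that of pair-fed animals. Extracellular matrix genes were lower in RYGB-Success, by a mean of -1.16 over 31 measured members, with 28 of 31 lower (camera adjusted p = 2.93e-20, and adjusted p = 0.297 with an estimated correlation). Preadipocyte and fibroblast markers were lower in 11 of 11 members, with a mean of -1.58 and a group level of 10.60 ± 0.51 against 12.18 ± 0.24 (SD, n = 3; adjusted p = 2.65e-13, and adjusted p = 0.297 with an estimated correlation). Both calls were also lost with fry (adjusted p = 0.218 and 0.177), and held under the other 19 of 21 alternatives. With the epithelium marker level as a covariate the matrix mean was -0.70. Among the members, Timp2, an inhibitor of matrix proteases, had a change of -1.98 ± 0.40, Fn1, fibronectin, -2.48 ± 0.58, Loxl1, an elastin crosslinking enzyme, -1.91 ± 0.42, and Mfap5, a microfibril protein, -2.93 ± 0.50. Adjusted over the list alone, 18 matrix members and 8 fibroblast markers passed. Over all probe sets, 0 did.

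Markers of other cell types moved in the same arrays. Skin and mammary epithelium markers were higher in 11 of 11 members by a mean of 3.19, at 9.42 ± 2.83 against 6.23 ± 1.09 (adjusted p = 1.69e-07, and adjusted p = 0.316 with an estimated correlation). Over every gene of the list on the array, the level by array was 5.8, 9.9 and 9.2 in RYGB-Success and 5.2, 4.9 and 6.0 in Pair-Fed, and the mean was 4.81 without Success 1. With arrays held at no less than the filter's signal the mean was 2.62. Krt5 and Krt18, keratins of epithelial cells, had changes of 3.02 ± 0.96 and 3.23 ± 1.23, with Pair-Fed means under the filter's signal and folds of at least 5.50 and 6.05. B and T lymphocyte markers (mean 1.47, 10 of 10 higher, adjusted p = 8.78e-05) and blood cell markers (mean 1.43, 5 of 5 higher, adjusted p = 0.000897) were also higher (adjusted p = 0.316 with an estimated correlation for each). Without Success 3 the lymphocyte call was lost (mean 0.67, adjusted p = 0.071) and the blood cell mean was 0.83. Among blood markers, Hbb, a globin, passed over the list alone with 1.69 ± 0.42.

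Ribosomal protein genes were higher in 28 of 28 members by a mean of 0.37 (adjusted p = 2.39e-07, and adjusted p = 0.343 with an estimated correlation), and the sign turned when arrays were centred on their median (-0.01). Respiratory chain genes were lower in 41 of 48 members by a mean of -0.30 (adjusted p = 0.000557, and adjusted p = 0.716 with an estimated correlation), and the call was lost with array brightness as a covariate (-0.08, adjusted p = 0.30). Macrophage and inflammation genes had a mean of -0.41 with 22 of 28 lower (adjusted p = 0.00318), skeletal muscle markers 1.36 (adjusted p = 0.00414) and endothelial markers 0.43 (adjusted p = 0.0134). For these 3 lists the adjusted p = 0.716 with an estimated correlation. The macrophage call was lost without Pair-Fed 1 (mean -0.12, adjusted p = 0.36) or Success 2 (mean -0.26, adjusted p = 0.089) and with brightness (-0.16) or epithelium (0.06) as a covariate, the muscle call without Pair-Fed 3 (adjusted p = 0.065) and with a pseudocount (0.54, adjusted p = 0.165), its mean being 0.39 with arrays held at no less than the filter's signal, and the endothelial call without Pair-Fed 1, Pair-Fed 2 or Success 1 (adjusted p = 0.055 to 0.23). Without Pair-Fed 3 the macrophage and endothelial means were -0.65 and 0.65, and the endothelial call was also lost under median centring (0.06, adjusted p = 0.058) and with brightness as a covariate (0.28, adjusted p = 0.131). Mast cell markers (mean -0.81, adjusted p = 0.0325), glycolysis (0.39, adjusted p = 0.0454) and cell cycle (0.40, adjusted p = 0.0454) lay near the threshold (adjusted p = 0.316, 0.316 and 0.716 with an estimated correlation). Lists matched on mean expression had medians of 0.15 for cell cycle and -0.11 for the respiratory chain. The glycolysis and cell cycle calls were each lost under 13 of 21 alternatives, with means down to 0.02 for each under median centring, and the mast cell call under 5 of 20. Among single arrays, the calls were lost without Pair-Fed 1 or Success 1 for mast cells, without Pair-Fed 2, Pair-Fed 3 or Success 3 for glycolysis, and without Pair-Fed 1, Pair-Fed 3 or Success 3 for cell cycle (adjusted p = 0.055 to 0.62). Without Success 1 the endothelial and mast cell means were 0.27 and -0.54, and without Success 3 the cell cycle mean was 0.12.

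No single probe set passed with limma in this comparison (0 of 18625), with 905 at an unadjusted p under 0.05, 342 higher and 563 lower, where chance gives 931. With array weights 39 passed, among them Alox15, Mme, Mfap5, Timp2 and Fn1 (adjusted p = 0.036 to 0.043), and 22 without Success 1. The groups did not overlap for 18.6% of probe sets, where chance gives 10%. The lowest p-values among higher genes belonged to Alox15, a lipoxygenase, at 3.99 ± 0.85 (adjusted p = 0.482), and Fasn, fatty acid synthase, at 2.93 ± 0.67 for one probe set and 2.14 ± 0.50 for the other. Cdca7l (3.22), Oprpn (5.36), Cd69 (2.79) and Car2 (2.99) followed. Pair-Fed means of Alox15, Cdca7l, Oprpn and Cd69 lay under the filter's signal, and their folds were at least 10.6, 4.02, 21.3 and 3.31. Lower values were led by Mme, the peptidase neprilysin, at -2.31 ± 0.36 (adjusted p = 0.479), then LOC102555145 (-2.17), Mfap5, Ecm1 (-2.28), Plac9 (-2.13) and Dclk1 (-1.97). Of these, Mfap5, Plac9, Fasn and Car2 passed without Success 1 (adjusted p = 0.029, 0.029, 0.021 and 0.0081). The anchors Adipoq (0.12), Scd (0.26), Ucp2 (0.49), Ccl2 (-1.13), Pparg (-0.44) and Lpl (-0.08) did not pass, and Adipoq had -0.25 under quantile normalization. The median over all probe sets was 0.11 here, -0.02 after quantile normalization and -0.27 after median centring. Among probe sets at an unadjusted p under 0.05, 37.8% were higher, 30.5% after quantile normalization and 18.6% after median centring.

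Fail against Pair-Fed fat asked the same of animals regaining weight. Skeletal muscle markers were higher in RYGB-Fail fat in 15 of 15 members by a mean of 5.59, at 11.64 ± 3.05 against 6.05 ± 0.74 (adjusted p = 5.37e-39, and adjusted p = 0.107 with an estimated correlation). Adjusted over the list alone 14 passed, and 0 did over all probe sets. Atp2a1, the calcium pump of fast muscle, had a change of 7.81 ± 1.24, Mybpc2, a myosin-binding protein, 7.42 ± 1.18 (adjusted p = 0.40 for each), and Ckm, muscle creatine kinase, 7.82 ± 1.57. Pair-Fed signals were 5.68 to 51.1 for Atp2a1, 9.30 to 50 for Mybpc2 and 4.22 to 63.7 for Ckm, under the filter's 88.9, so these were at least 41.3-fold, 37.5-fold and 32.3-fold, and the list's mean with arrays held at no less than that signal was 4.44. Over every gene of the list on the array, the level differed between the RYGB-Fail arrays, at 11.7, 14.1 and 8.0, against 5.8, 6.1 and 4.7 in Pair-Fed. Ckm signals on the RYGB-Fail arrays were 3792, 23944 and 260.

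**Figure D2:**
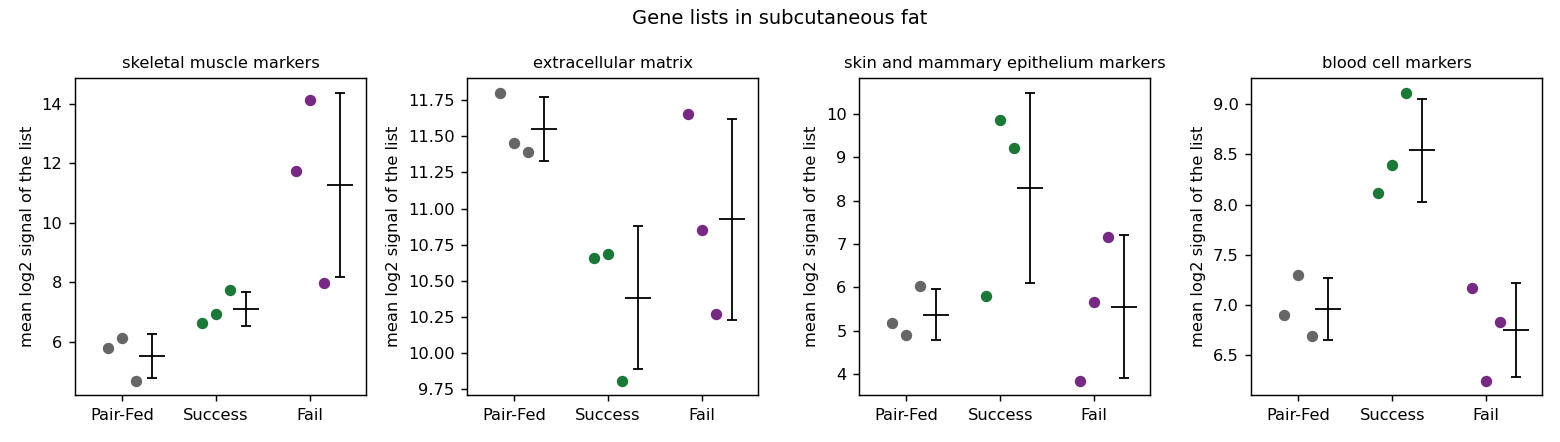
Mean log2 signal over every gene on the array of 4 gene lists, by group, with points for single fat arrays and black bars for the mean ± SD of 3 arrays. Skeletal muscle markers lay at 11.7, 14.1 and 8.0 in RYGB-Fail against 5.8, 6.1 and 4.7 in Pair-Fed, and epithelium markers at 5.8, 9.9 and 9.2 in RYGB-Success.

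In the same comparison, beside the muscle shift of 5.59, citric acid cycle genes were higher by a mean of 0.37 in 14 of 15 members (adjusted p = 0.00271), and respiratory chain genes by 0.16 in 33 of 48 (adjusted p = 0.0212; adjusted p = 0.857 with an estimated correlation for both). Both turned negative without Fail 2, the array with the most muscle signal, to -0.13 and -0.28. Without Fail 1 they were 0.63 and 0.31, and without Fail 3 they were 0.60 and 0.45. With the muscle marker level as a covariate they were -0.66 and -0.95. The respiratory chain call was also lost without Pair-Fed 3 (adjusted p = 0.21), with no filter (adjusted p = 0.056) and under median centring (adjusted p = 0.060). Extracellular matrix genes had a mean of -0.62 with 28 of 31 lower (adjusted p = 7.36e-07) and fibroblast markers -0.73 with 11 of 11 lower (adjusted p = 0.00025). Each had an adjusted p = 0.857 with an estimated correlation, and each call was lost without Fail 3 (means -0.29 and -0.45, adjusted p = 0.091 and 0.11). Without Fail 1 the means were -0.98 and -1.15. With array weights they were -0.27 and -0.36, where the fibroblast call was lost (adjusted p = 0.059), as it was with the muscle covariate (adjusted p = 0.080). Ribosomal proteins had a mean of -0.29 with 26 of 28 lower (adjusted p = 8.73e-05, and adjusted p = 0.857 with an estimated correlation), lost without Fail 2 (-0.16, adjusted p = 0.075), with quantile normalization (-0.09, adjusted p = 0.87) and with the muscle covariate (-0.13, adjusted p = 0.65). Lists matched on mean expression had a median of -0.34 for ribosomal proteins, -0.19 for matrix genes and -0.22 for fibroblast markers.

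Adipocyte markers were lower in 9 of 9 members by a mean of -0.47 (adjusted p = 0.0212) and adipokines by -0.34 in 16 of 20 (adjusted p = 0.0277; adjusted p = 0.857 with an estimated correlation for both). The adipokine list holds all the adipocyte markers, so these calls are not separate results. Lists matched on mean expression had medians of -0.28 and -0.21. Fabp4, a fatty acid carrier of adipocytes, had -0.69 ± 0.34, and Cd36, a fatty acid transporter, -1.13 ± 0.39. Macrophage genes had a mean of -0.43 with 26 of 28 lower (adjusted p = 0.00649, and adjusted p = 0.857 with an estimated correlation). Clock genes had a mean of 0.27 with 12 of 15 higher (adjusted p = 0.0212, and adjusted p = 0.399 with an estimated correlation). Adipocyte and adipokine calls were lost without Pair-Fed 2, Fail 1 or Fail 2 (adjusted p = 0.26 to 0.57), the macrophage call without Pair-Fed 1 or Fail 3 (means -0.13 and -0.06, adjusted p = 0.64 and 0.94) and with array weights (-0.04, adjusted p = 0.94), and the clock call without Pair-Fed 1 or any RYGB-Fail array (adjusted p = 0.077 to 0.10). Without Fail 3 the adipocyte and adipokine means were -0.81 and -0.51, and the macrophage mean was -0.67 without Pair-Fed 3 and -0.80 without Fail 1. The adipocyte mean was -0.23, -0.29 and -0.30 without Pair-Fed 2, Fail 1 and Fail 2, and the adipokine mean -0.17 without Pair-Fed 2. Both calls were also lost with the mean of all probe sets of a gene and under quantile normalization (adjusted p = 0.067 to 0.090), and the adipokine call at the filter of the upper 40% (adjusted p = 0.065). Both means turned to 0.60 and 0.25 with the muscle covariate. The clock call was also lost with no filter and with the muscle covariate (adjusted p = 0.056 and 0.46).

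No probe set passed with limma (0 of 18625), with 501 at an unadjusted p under 0.05, 264 higher and 237 lower. Array weights gave 35, and 42 passed without Fail 3. The groups did not overlap for 6.90% of probe sets, where chance gives 10%. Beside the muscle genes Mybpc2, Atp2a1, Myl1 (4.91), Neb (4.19), Tnnc2 (6.69) and Ckm, the lowest p-values were those of Rbp7 (-1.04), Atl3 (-1.34), Blvrb (-1.14), Cidea (-1.27), Prc1 (-1.47) and Sncg (-1.42), all with an adjusted p = 1.00. The 6 muscle genes passed without Fail 3 (adjusted p = 0.00021 to 0.017) and with array weights. Folds were at least 14.3 for Neb and 56.2 for Tnnc2, whose Pair-Fed means lay under the filter's signal. The anchors Adipoq (-0.23), Fasn (0.35), Scd (0.03), Ucp2 (-0.36), Ccl2 (-0.48), Pparg (-0.56) and Lpl (-0.46) did not pass. The higher share at an unadjusted p under 0.05 was 52.7%, 53.9% after quantile normalization and 72.7% after median centring, where the median over all probe sets was -0.09, -0.11 and -0.16.

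Success against Fail fat set the animals losing weight against those regaining it. Skeletal muscle markers were lower in RYGB-Success in 14 of 15 members by a mean of -4.23 (adjusted p = 5.17e-20), and blood cell markers were higher in 5 of 5 by 2.13 (adjusted p = 3.19e-05; adjusted p = 0.269 with an estimated correlation for both). Over the list alone 13 muscle members passed, and 3 blood members, namely Hbb at 2.39 ± 0.42, Alas2, an enzyme of haem synthesis in red cells, at 3.82 ± 1.00, and S100a8, a leukocyte protein, at 2.32 ± 0.84. Over all probe sets 0 passed. RYGB-Fail means of Alas2 and S100a8 lay under the filter's signal, and their folds were at least 4.36 and 3.29. With arrays held at no less than that signal the list means were -4.05 for muscle and 1.42 for blood. Epithelium markers were higher in 11 of 11 by 3.34 (adjusted p = 2.33e-07, and adjusted p = 0.380 with an estimated correlation), and by 2.48 when held at that signal.

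Beside these shifts, ribosomal protein genes were higher in 28 of 28 members by a mean of 0.66, 14 over the list alone (adjusted p = 1.05e-16, and adjusted p = 0.269 with an estimated correlation). Lists matched on expression had a median of 0.36, and the ribosomal mean was 0.30 under quantile normalization and 0.36 under median centring. Respiratory chain genes were lower in 45 of 48 by -0.46 (adjusted p = 1.28e-08, and adjusted p = 0.456 with an estimated correlation) and citric acid cycle genes by -0.38 in 14 of 15 (adjusted p = 0.0029, and adjusted p = 0.513 with an estimated correlation). Without Fail 2 these means were -0.02 and 0.12, and neither passed (adjusted p = 0.66 for each), while without Fail 3 they were -0.75 and -0.61, and the citric acid cycle mean was -0.64 without Fail 1. With the muscle marker level as a covariate they turned to 0.38 and 0.40, and the citric acid cycle call was lost with brightness as a covariate (-0.23, adjusted p = 0.058). Matrix genes had a mean of -0.54 with 24 of 31 lower (adjusted p = 2.33e-07, and adjusted p = 0.456 with an estimated correlation), and fibroblast markers -0.85 with 11 of 11 lower (adjusted p = 1.77e-05, and adjusted p = 0.403 with an estimated correlation), lost without Fail 1 (mean -0.43, adjusted p = 0.051) and with the muscle covariate (adjusted p = 0.11). The matrix call was lost with the muscle or epithelium covariate (means -0.13 and -0.06, adjusted p = 0.20 and 0.19). The matrix mean was -0.18 without Fail 1, -0.87 without Fail 3 and -0.26 without Success 3, and the fibroblast mean was -0.56 without Success 3.

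Lipogenesis genes were higher in 16 of 22 members by a mean of 0.45 (adjusted p = 0.00991, and adjusted p = 0.456 with an estimated correlation). Fasn at 1.79 ± 0.50 and Acly, which supplies acetyl-CoA for fatty acids, at 1.12 ± 0.31 passed over the list alone, and over all probe sets without Fail 3 (adjusted p = 0.041 and 0.043). The list's call was lost without Fail 1 or Success 2 (means 0.35 and 0.07, adjusted p = 0.16 and 0.68), under quantile normalization (adjusted p = 0.066) and with each of the 3 covariates (adjusted p = 0.052 to 0.60), and its mean was 0.72 without Success 3. Cell cycle (0.68, adjusted p = 0.00333), endothelial (0.56, adjusted p = 0.0029), lymphocyte (1.29, adjusted p = 0.00527) and leptin and cytokine signalling lists (0.46, adjusted p = 0.0268) were higher (adjusted p = 0.456 with an estimated correlation for each). Mast cell markers were lower by -0.86 (adjusted p = 0.00923, and adjusted p = 0.380 with an estimated correlation). Leaving out single arrays ended each of these 5 calls, namely Fail 1, Fail 2 or Success 3 for cell cycle, Fail 2 or Success 1 for endothelium, Success 3 for lymphocytes, Fail 2, Fail 3 or Success 2 for leptin signalling, and Fail 1 or Success 1 for mast cells (adjusted p = 0.053 to 0.49). The leptin signalling mean was 0.71 without Fail 1, and the cell cycle mean 1.13 without Fail 3. Without Fail 2 the cell cycle and endothelial means were 0.32 and 0.25, and without Success 3 the cell cycle and lymphocyte means were 0.41 and 0.49. The cell cycle, endothelial and lymphocyte calls were lost with the brightness or the muscle covariate (adjusted p = 0.055 to 0.40), the first 2 turning to -0.23 and -0.23 with the muscle covariate. The cell cycle and lymphocyte calls were lost with the epithelium covariate (adjusted p = 0.38), the mast cell call with the muscle covariate (adjusted p = 0.125), and the leptin signalling call with no filter, at the filter of the upper 40%, with array weights and with the muscle covariate (adjusted p = 0.066 to 0.31).

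No probe set passed with limma (0 of 18625), with 1060 at an unadjusted p under 0.05, 638 higher and 422 lower. Array weights gave 26, and 13 passed without Success 1. Without Fail 3, 1116 passed. The groups did not overlap for 7.87% of probe sets, where chance gives 10%. Hbb had the lowest p among higher genes (adjusted p = 0.517), with Fgl2 (1.47), Vasp (1.07), Rbp7 (1.32), Map4k2 (2.05) and Plin2, a lipid droplet coat protein (2.17). Lower values were led by Neb (-4.09), LOC102555145 (-1.76), Mme (-1.74), Meg3 (-3.11), Ttn (-4.83) and Mybpc2 (-5.46). RYGB-Success means of Neb, Meg3, Ttn and Mybpc2 lay under the filter's signal, and these were at least 11.4-fold, 4.40-fold, 18-fold and 34.6-fold lower. Without Fail 3, 11 of these 12 passed, with adjusted p = 0.005 to 0.037, and Plin2 passed without Success 1 (adjusted p = 0.011). The anchors Adipoq (0.35), Scd (0.23), Ucp2 (0.85), Ccl2 (-0.65), Pparg (0.12) and Lpl (0.38) did not pass, and Adipoq and Lpl had -0.03 and -0.01 under quantile normalization. The higher share was 60.2%, 47.7% after quantile normalization and 26.7% after median centring, with a median over all probe sets of 0.17, 0.08 and -0.13. An F test in limma over the 3 groups gave 0 probe sets, 869 at an unadjusted p under 0.05, 53 with array weights, 202 without Fail 3 and 13 without Success 1. Lep and Ucp1 lay below the signal filter in fat and were not tested.

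Success against Pair-Fed hypothalamus gave 2 probe sets that passed. Alox15, the lipoxygenase named above in fat, rose by 4.39 ± 0.57 on the log2 scale (9.98 ± 1.00 against 5.59 ± 0.86, SD, n = 3; adjusted p = 0.0214). Its Pair-Fed signals were 34.2 to 96.1, with a mean under the filter's 52.7, so the rise was at least 15.7-fold, and the change was 3.19 with a pseudocount. Pkig, an inhibitor of protein kinase A, fell by 2.07 ± 0.21 on the log2 scale (11.10 ± 0.43 against 13.17 ± 0.14; adjusted p = 0.00223). Hcrt, the precursor of the orexin peptides that promote feeding and wakefulness, had a change of 3.13 ± 0.49 (adjusted p = 0.0887) and Pmch, the precursor of the appetite-promoting melanin-concentrating hormone, 1.83 ± 0.34 (adjusted p = 0.173). Pair-Fed signals of Hcrt were 69.0, 48.0 and 51.7, about the filter's 52.7, and its signals in fat were 5.43 to 232. The size of the Hcrt change is therefore uncertain. Both groups' arrays were apart for these 4 genes, and neither peptide gene passed over all probe sets. The Alox15 call was lost without Pair-Fed 2, Pair-Fed 3, Success 1 or Success 3 (adjusted p = 0.13 to 0.24), and Hcrt and Pmch passed without Success 2 (adjusted p = 0.028 and 0.048).

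**Figure D3:**
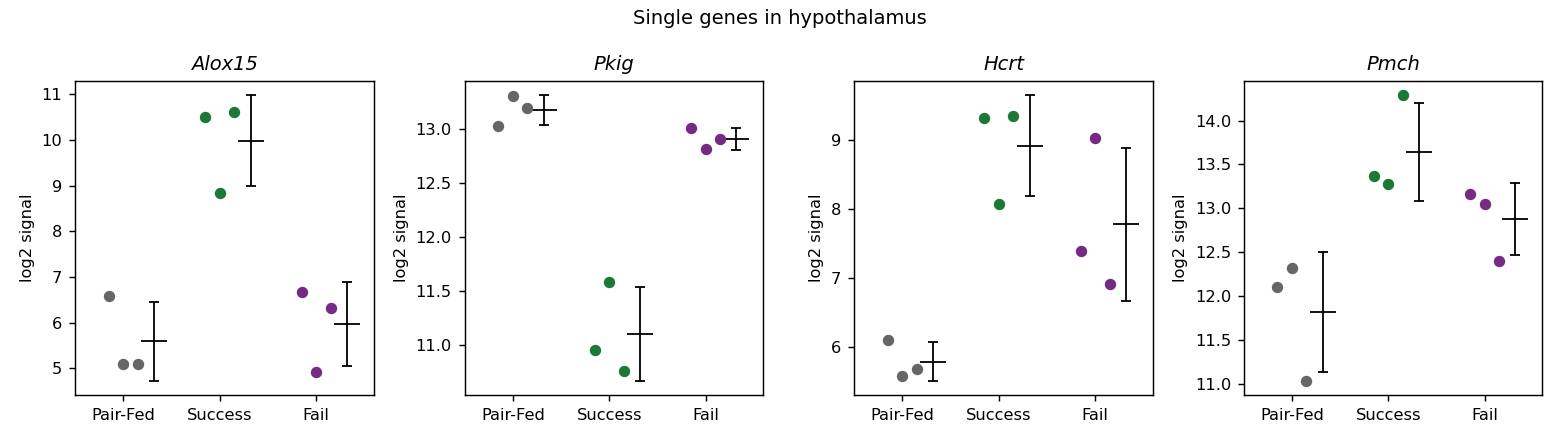
Log2 signal of Alox15, Pkig, Hcrt and Pmch by group, with points for single hypothalamus arrays and black bars for the mean ± SD of 3 arrays. Alox15 lay at 9.98 ± 1.00 in RYGB-Success against 5.59 ± 0.86 in Pair-Fed, and Pkig at 11.10 ± 0.43 against 13.17 ± 0.14.

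Other genes with low p-values were Ces5a (1.85), Alas2 (3.13) and Slco1a5 (1.84) among higher values, and Grm5, a glutamate receptor (-1.35), Chn1 (-1.14), Nr4a3 (-1.56), Ube3d (-1.33) and Ccsap (-1.17) among lower ones. The Pair-Fed mean of Alas2 lay under the filter's signal, and its fold was at least 5.50. Ces5a, Alas2 and Chn1 passed without Success 2 (adjusted p = 0.041, 0.047 and 0.033), Alas2 also without Pair-Fed 1 (adjusted p = 0.025) and Grm5 without Success 1 (adjusted p = 0.023). Of the feeding peptide anchors, Npy (-0.16), Cartpt (0.90), Crh (0.68), Mc4r (-0.91) and Lepr (-0.28, with a second probe set of the opposite sign) did not pass. Over the orexigenic list alone, Hcrt, Pmch and Gal, the peptide galanin (1.22 ± 0.36), were higher and Cnr1, the cannabinoid receptor (-1.03 ± 0.26), was lower, but the list itself was not called (mean 0.56, adjusted p = 0.0948, and adjusted p = 0.403 with an estimated correlation). Among neurosecretory hormones Npvf (1.66 ± 0.33), Vip (0.86 ± 0.23) and Oxt, oxytocin (1.77 ± 0.60), were higher over the list alone and Pam (-0.88 ± 0.28) lower, with no call for the list (mean 0.44, adjusted p = 0.0819).

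Respiratory chain genes were higher in 38 of 48 members by a mean of 0.23, with 7 over the list alone, led by Ndufa1 at 1.12 ± 0.24 (camera adjusted p = 0.0128, fry adjusted p = 0.0131, and adjusted p = 0.231 with an estimated correlation). The sign turned under median centring (-0.01), and the call was lost without Success 2 (adjusted p = 0.056). Macrophage genes had a mean of 0.46 with 18 of 22 higher (adjusted p = 0.0243, and adjusted p = 0.372 with an estimated correlation), with Lyz2, a macrophage lysozyme, at 0.84 ± 0.24. In the same arrays globins had a mean change of 1.40 ± 0.46 over the 2 measured, and blood leukocyte and platelet genes 1.91 ± 0.31 with 7 of 7 higher. These lists were both chosen after the data were seen. Only 7 of 34 leukocyte and platelet genes were on the array and past the filter, and 4 of these 7 are also in the fixed lists. The filter's mean signal included the RYGB-Success arrays, so genes high there pass more readily. Immediate early genes, which neuronal activity induces, had a mean of -0.28 with 14 of 22 lower, including Egr2 at -2.09 ± 0.41 and Nr4a1 at -1.43 ± 0.42, with 5 passing over the list alone (adjusted p = 0.0243, and adjusted p = 0.372 with an estimated correlation). Markers of other forebrain regions had a mean of -0.64 in the same arrays, with 7 of 10 lower, and did not pass (adjusted p = 0.0819, and adjusted p = 0.372 with an estimated correlation), with Neurod2, a forebrain transcription factor, at -2.14 ± 0.62. Leaving out Pair-Fed 3, Success 2 or Success 3 ended the macrophage call and Pair-Fed 3, Success 1 or Success 2 the immediate early call (adjusted p = 0.055 to 0.17), with the immediate early mean at -0.13 without Success 1. The macrophage call was also lost with no filter, at the filter of the upper 40% and with array weights (adjusted p = 0.072 to 0.088), and the immediate early call under median centring (-0.51, adjusted p = 0.070). The count of 3 lists became 0 without Success 2, 1 without Pair-Fed 3, 5 without Pair-Fed 2 and 7 without Success 1. Ndufa1 passed over all probe sets without Success 2 (adjusted p = 0.048). The test counted 2447 probe sets at an unadjusted p under 0.05, 1293 higher and 1154 lower, and 18% had groups apart, where chance gives 10%. The count of 2 became 65 without Success 2, and 1 without Pair-Fed 2, Pair-Fed 3 or Success 3. The higher share was 52.8%, 46.1% after quantile normalization and 12.2% after median centring, with a median over all probe sets of 0.05, -0.01 and -0.19.

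Fail against Pair-Fed hypothalamus gave 0 of 18625 probe sets with limma, with 445 at an unadjusted p under 0.05, 337 higher and 108 lower, and 0 with array weights. Camera at its preset correlation called 8 gene lists, and none of them passed with an estimated correlation. Macrophage genes were higher in 21 of 22 members by a mean of 0.51 (adjusted p = 2.72e-07) and microglia markers in 8 of 8 by 0.54, at 8.37 ± 0.02 against 7.83 ± 0.20 (adjusted p = 5.18e-06, fry adjusted p = 0.0387; adjusted p = 0.069 with an estimated correlation for both). C1qa and Tyrobp, genes of microglia, had changes of 0.77 ± 0.24 and 0.73 ± 0.30. Blood leukocyte and platelet genes had a mean of 1.00 ± 0.31 in these arrays, and globins -0.07 ± 0.46. Respiratory chain genes were higher in 41 of 48 by 0.19 (adjusted p = 0.000497, fry adjusted p = 0.0387, and adjusted p = 0.069 with an estimated correlation). Choroid plexus and ependyma markers were higher in 11 of 12 by 0.62 (adjusted p = 1.17e-05, and adjusted p = 0.140 with an estimated correlation), with Kcne2, a channel subunit of choroid plexus, at 1.36 ± 0.34 passing over the list alone. Immediate early genes were lower in 16 of 22 by -0.26 (adjusted p = 0.000201, and adjusted p = 0.140 with an estimated correlation), with Egr2 at -1.57 ± 0.41 over the list alone, beside the forebrain region markers given below.

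Interferon genes had a mean of 0.36 with 16 of 19 higher (adjusted p = 0.0102) and markers of other forebrain regions -0.35 with 8 of 10 lower (adjusted p = 0.0289), each with an adjusted p = 0.140 with an estimated correlation. Anorexigenic peptides and receptors had a mean of 0.31 with 12 of 15 higher (adjusted p = 0.042, and adjusted p = 0.156 with an estimated correlation), with Trh, thyrotropin-releasing hormone, at 1.18 ± 0.34 and Cartpt at 0.98 ± 0.40. These 3 calls were each lost without several single arrays, Pair-Fed 2, Pair-Fed 3, Fail 2 or Fail 3 for interferon, Pair-Fed 1, Pair-Fed 3, Fail 1 or Fail 2 for forebrain markers, and Pair-Fed 3, Fail 1 or Fail 2 for the anorexigenic list (adjusted p = 0.052 to 0.43). The forebrain mean was -0.15 without Fail 2 and the anorexigenic mean 0.19 without Pair-Fed 3. The anorexigenic and forebrain calls were lost under 10 and 11 of 19 alternatives, the former at a mean of 0.03 with no filter (adjusted p = 0.44), and the interferon call also with the beta-actin ratio as a covariate (adjusted p = 0.17). Without Pair-Fed 3 the count of lists was 5 in place of 8, and the choroid plexus mean 0.40. The genes with the lowest p were Mfrp (1.42), Hcrt (1.99 ± 0.49), Kcne2, Slco1a5 (1.33), Fxyd1 (0.93) and Tmem176a (0.95) among higher values and Egr2, Ube3d (-0.84), Nt5c (-1.24), Homer1 (-1.32), Hrk (-1.02) and Igsf10 (-0.96) among lower ones, all with an adjusted p = 1.00. Pmch had 1.05 ± 0.34, Npy 0.08, Crh 0.15, Mc4r 0.01 and Lepr -0.26. As in RYGB-Success, Hcrt and Pmch were higher over the orexigenic list alone (adjusted p = 0.014 and 0.0405), and the list was not called (mean 0.38, adjusted p = 0.078, and adjusted p = 0.354 with an estimated correlation). Groups were apart for 9.18% of probe sets, where chance gives 10%. The higher share was 75.7%, 63.9% after quantile normalization and 39.4% after median centring.

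Success against Fail hypothalamus gave 1 probe set, with 1120 at an unadjusted p under 0.05, 415 higher and 705 lower. Pkig fell by 1.81 ± 0.21 (11.10 ± 0.43 against 12.91 ± 0.10; adjusted p = 0.0116). The call was lost without any one RYGB-Fail array (adjusted p = 0.078 to 0.13) or Success 1 (adjusted p = 0.050), and when only these 6 arrays were fitted (adjusted p = 0.082). Alox15 had 4.01 ± 0.57 (adjusted p = 0.0582), and it passed without Success 2 (adjusted p = 0.015), where the count was 6, with array weights (adjusted p = 0.0029) and with a pseudocount (adjusted p = 0.0051). Alas2 (2.40), Fam20c (1.43), Acer2 (1.98), Esf1 (0.92) and Senp1 (2.23, at least 2.29-fold) followed, and Bloc1s2 (-1.52), Dhx58 (-1.67), Spast (-1.35), Ipo8 (-1.76) and Rab7b (-1.44) among lower values. Other probe sets of Dhx58 and Ipo8 had the opposite sign, and Bloc1s2 passed without Success 2 (adjusted p = 0.029). Hcrt had 1.14 ± 0.49, Pmch 0.77 ± 0.34, Npy -0.24, Cartpt -0.08, Crh 0.53, Mc4r -0.92 and Lepr -0.02.

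In that comparison glycolysis genes were higher in 14 of 16 members by 0.23 (adjusted p = 0.014), angiogenesis and hypoxia genes in 14 of 16 by 0.27 (adjusted p = 0.0183) and endothelial markers in 9 of 11 by 0.45 (adjusted p = 0.0183; adjusted p = 0.724 with an estimated correlation for all 3). Slc2a1, the glucose transporter of the blood-brain barrier, had 0.60 ± 0.25 and Vwf, an endothelial clotting protein, 1.64 ± 0.52. In the same arrays globins had a mean of 1.47 ± 0.46 with 2 of 2 higher, and blood leukocyte and platelet genes 0.91 ± 0.31 with 6 of 7 higher. With array weights the glycolysis, angiogenesis and endothelial calls were all lost (means 0.06, 0.20 and 0.22, adjusted p = 0.48, 0.175 and 0.40). The endothelial call was also lost at the filter of the upper 40% and with the beta-actin ratio as a covariate (adjusted p = 0.14 and 0.058). The glycolysis call was lost without Success 3 (mean 0.04, adjusted p = 0.57), the hypothalamus array with the lowest weight (0.331) and median correlation (0.904), and the other 2 without Fail 1, Fail 3, Success 2 or Success 3 (adjusted p = 0.067 to 0.29), with an endothelial mean of 0.27 without Fail 1. The count of 3 lists became 1 without Success 2 or Success 3. The higher share was 37.1%, 35.4% after quantile normalization and 11% after median centring, with a median over all probe sets of 0.01, 0.00 and -0.11. Groups were apart for 10.5% of probe sets, where chance gives 10%. The F test over the 3 groups gave 2 probe sets and 1430 at an unadjusted p under 0.05, with 5 without Fail 2, 4 without Success 2 and 1 without Pair-Fed 2, Pair-Fed 3, Fail 3 or Success 3. Pomc lay below the signal filter in hypothalamus, with signals of 3.66 to 62.7, and Agrp had no probe set with a single symbol.

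The changes against Pair-Fed in the Success and Fail animals correlated across probe sets with r of 0.35 in fat and 0.54 in hypothalamus, where genes are not independent replicates. Both comparisons share the Pair-Fed arrays, and 100 simulations of unchanged groups against a simulated shared control gave 0.50 in each tissue. That value follows from the equal spread given to the simulated groups and holds no information on these arrays. The covariance was 0.139 in fat against 0.186 simulated, and 0.103 in hypothalamus against 0.072. The Pair-Fed arrays were too few to split, so part of any excess may come from the shared controls. The test of the difference between tissues gave 0 of 15531 probe sets with limma in each comparison, with 1283, 466 and 1002 at an unadjusted p under 0.05 for Success against Pair-Fed, Fail against Pair-Fed and Success against Fail. Array weights gave 35, 12 and 4. Without fat Success 1 the first and last counts were 41 and 22, and without fat Fail 3 the last 2 were 17 and 132.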

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

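The 6 tests of muscle tissue, array brightness, residual blood, immature red cells, dissection and RNA quality were chosen after the results were seen, and the gene sets or bounds of the blood, red cell and dissection tests were revised once first values were known. The splits of the arrays were planned.

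The following gene lists had changes that differed between fat and hypothalamus by camera on the test of the difference itself, given as fat minus hypothalamus in mean log2. For RYGB-Success against Pair-Fed these were the respiratory chain at -0.53 (adjusted p = 1.29e-05, and adjusted p = 0.979 with an estimated correlation), macrophage genes at -0.97 (adjusted p = 4.26e-05, and 0.668) and extracellular matrix at -1.23 (adjusted p = 1.70e-07, and 0.667). For RYGB-Fail against Pair-Fed they were the citric acid cycle at 0.29 (adjusted p = 0.0221, and 0.982), macrophage genes at -0.99 (adjusted p = 1.66e-06, and 0.387), extracellular matrix at -0.65 (adjusted p = 0.00402, and 0.874), clock genes at 0.35 (adjusted p = 0.00736, and 0.220) and ribosomal proteins at -0.41 (adjusted p = 2.94e-06, and 0.387). For RYGB-Success against RYGB-Fail they were the respiratory chain at -0.49 (adjusted p = 7.19e-08, and 0.877), the citric acid cycle at -0.52 (adjusted p = 0.00111, and 0.877), extracellular matrix at -0.59 (adjusted p = 0.00111, and 0.877) and ribosomal proteins at 0.59 (adjusted p = 3.65e-10, and 0.359). The second p in each bracket is with an estimated correlation, where none passed. The skeletal muscle shifts of 5.59 in RYGB-Fail against Pair-Fed and -4.23 in RYGB-Success against RYGB-Fail lay in the same fat arrays. For RYGB-Success against Pair-Fed, epithelium markers were at 3.19 in fat. With their level as a covariate the fat macrophage mean was 0.06 and the matrix mean -0.70. In hypothalamus, blood leukocyte and platelet genes were above Pair-Fed by 1.91 ± 0.31 in RYGB-Success and 1.00 ± 0.31 in RYGB-Fail. In fat the citric acid cycle mean of RYGB-Fail against Pair-Fed turned to -0.13 without Fail 2, and for RYGB-Success against RYGB-Fail the respiratory chain and citric acid cycle means were -0.02 and 0.12 without Fail 2 and 0.38 and 0.40 with the muscle marker level as a covariate. The list differences between tissues were not rerun under alternatives.

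Skeletal muscle markers were higher in RYGB-Fail than in Pair-Fed fat by 5.59, and by 4.44 with arrays held at no less than the filter's signal. With each array's median signal as a covariate the change was 5.81. Median signals in RYGB-Fail, 102, 98.2 and 288, lay on both sides of the 126 to 147 in Pair-Fed. That covariate could hardly move the change, so the test does not decide on array brightness. Fail 2, the array with the most muscle signal, had the lowest median signal of the fat arrays. Muscle tissue in the fat samples had the values it needs, with 19 of 19 measured muscle genes outside the list higher, by a mean of 3.07 ± 1.06. The log2 ratio between the RYGB-Fail arrays richest in muscle had an SD of 0.75 over 14 members. Only 19 of 38 such genes were on the array and past the filter, whose mean signal included the RYGB-Fail arrays. Genes high in RYGB-Fail alone pass more readily, so the 19 of 19 and the mean depend in part on the filter. A response of fat itself to the treatment was not tested and stays open.

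Alox15, Alas2 and globin genes were higher in RYGB-Success than in Pair-Fed. Residual blood in the tissue had the values it needs in hypothalamus, where leukocyte and platelet genes were higher by 1.91 ± 0.31 and globins by 1.40 ± 0.46, a difference of 0.51 ± 0.47. Only 2 of 10 globins and 7 of 34 leukocyte and platelet genes were measured there, after a filter that favours genes high in RYGB-Success. Of these 7 genes, 4 are also in the fixed lists, and the groups overlapped for Hbb. Alox15 was higher by 4.39 and Alas2 by 3.13 in these arrays. Whether blood accounts for changes larger than that of the globins was not tested. The blood test was set for hypothalamus alone. In fat of RYGB-Success against Pair-Fed, the 2 measured globins were higher by 1.24 ± 0.60. Leukocyte and platelet genes were higher there by 1.08 ± 0.49, with 14 of 16 higher. In RYGB-Fail hypothalamus the leukocyte and platelet genes were higher by 1.00 ± 0.31, with the 2 measured globins at -0.07 ± 0.46. The difference between them was not tested there, so whether these genes moved without globins is not settled. Blood richer in immature red cells cannot be told apart, because the other erythroid genes had means of 0.25 ± 0.16 in fat and 0.26 ± 0.08 in hypothalamus, between the bounds set for either answer. An effect of the treatment was not tested.

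Hcrt and Pmch were higher in RYGB-Success than in Pair-Fed hypothalamus, though neither passed over all probe sets, and in RYGB-Fail they were at 1.99 and 1.05. Pair-Fed signals of Hcrt, 48.0 to 69.0, lay about the filter's 52.7, so the size of its change is uncertain. With the 3' to 5' ratio of beta-actin as a covariate Hcrt was at 2.97. These ratios overlapped, at 10.1, 179 and 30.5 in Pair-Fed and 34.0, 48.5 and 6.65 in RYGB-Success. That covariate could hardly move the change, and ratios of other controls were not used, so the test does not decide on RNA quality. A dissection that took more lateral or posterior hypothalamus cannot be told apart, because 12 other markers of these areas had a mean of 0.21 ± 0.19, 6 higher and 6 lower. These 12 were the measured ones of 22, and 7 of them are also in the fixed lists. By limma 5 of the 12 had an unadjusted p under 0.05, where 2447 of all 18625 probe sets did. Markers of other forebrain regions had means of -0.64 in these arrays, with Neurod2 at -2.14, Adora2a at -1.54 and Slc17a7 at -0.95, and -0.35 in RYGB-Fail, and Slc6a3, the dopamine transporter, was at 2.79 ± 1.15 in RYGB-Success, and a dissection shifted in another way was not tested. An effect of the treatment on these neurons was not tested.

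Each comparison of 3 against 3 arrays has 10 splits, too few for a share under 0.05. The real grouping is 1 of the splits and is included wherever splits that met a count are given. In fat the real counts of probe sets were 0 for RYGB-Success against Pair-Fed, 0 for RYGB-Fail against Pair-Fed and 0 for RYGB-Success against RYGB-Fail, and the highest of the others gave 0, 0 and 550. Every split meets a count of 0, so the 10 of 10 found for each was fixed beforehand and says nothing about chance. These counts are from limma, with 905, 501 and 1060 at an unadjusted p under 0.05 and 39, 35 and 26 with array weights. For fat lists the real counts of 13, 10 and 14 were met by 5, 2 and 4 splits, with highest others of 14, 12 and 16. In hypothalamus the probe set counts of 2, 0 and 1 were met by 1, 10 and 2 splits, with a highest other of 1 in each, and the list counts of 3, 8 and 3 by 3, 1 and 6 splits, with highest others of 10, 6 and 7. The 0 here is limma's, with 445 at an unadjusted p under 0.05 and 0 with array weights, and its 10 of 10 was likewise fixed beforehand.

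For the F tests 100 splits were used, the real grouping included. In hypothalamus chance was not excluded, with a real count of 2, 9 of 100 splits as large and a highest other of 14. In fat the real count was 0 by limma, with 869 at an unadjusted p under 0.05, 53 with array weights and a highest other of 424. For the difference between tissues the real counts of 0 by limma, with 1283, 466 and 1002 at an unadjusted p under 0.05 and 35, 12 and 4 with array weights, had highest others of 0, 1 and 293. Any split meets a count of 0, so the 100 of 100 found for fat and for each difference between tissues tested nothing about chance. The splits with 550, 424 and 293 calls point to a structure of the samples. Which arrays make it, and whether a single array does, was not tested.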

How the results depend on the processing

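The covariates for array brightness, muscle markers, epithelium markers and the beta-actin ratio were chosen after seeing the data, and the other alternatives were planned. Of the counts under alternatives, 253 lay within 1.5 times the reported one and 74 did not. Of the gene values, 5129 kept direction and side of the threshold, 92 gained a call and 9 lost one. The sign turned for 87 that had neither a call nor, as reported, an unadjusted p under 0.05, and for 3 others. Of the list values, 768 kept both, 247 lost the call and 14 turned. The cause was not tested except where named.

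With an estimated correlation the counts of lists became 0, 0 and 0 in fat, for Success against Pair-Fed, Fail against Pair-Fed and Success against Fail in this order, and 0, 0 and 0 in hypothalamus, by camera, with 13, 10, 14, 3, 8 and 3 at the preset correlation. With fry they were 0, 0 and 0 in fat, and 1, 2 and 0 in hypothalamus. Both tests use the spread of the list between arrays, which rests on 9 arrays. At the stricter filter, where fewer genes are tested, fat Success against Pair-Fed had 8 lists, and hypothalamus had 1 probe set for Success against Pair-Fed and 1 for the F test.

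With array weights, limma called 39, 35 and 26 probe sets in fat and 53 by the F test, 6 for Success against Pair-Fed and 6 for Success against Fail in hypothalamus with 1 list for the latter, and 35, 12 and 4 for the difference between tissues. Median centring gave 6 and 2 probe sets in these hypothalamus comparisons and 1 list for Success against Pair-Fed, and quantile normalization gave 9 lists for Success against Pair-Fed. Hypothalamus Success against Fail had 2 probe sets under quantile normalization, the pseudocount, no filter, 1 probe set per gene and the beta-actin covariate, and 0 in limma when only the 2 groups were fitted, where Success against Pair-Fed had 5. The robust variance model gave 1 by the F test.

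Under median centring fat ribosomal proteins in Success against Pair-Fed turned to -0.01 (-0.00668), and the hypothalamus respiratory chain to -0.01 (-0.00526), as centring subtracts the array medians. Cox7b in fat Success against Fail turned to -0.0727 under quantile normalization.

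With array brightness as a covariate, fat had 16 probe sets for Fail against Pair-Fed and 9 lists for Success against Fail. With the muscle marker level as a covariate, there were 1 and 2 probe sets for Fail against Pair-Fed and Success against Fail, and 6 lists for the former. Signs turned in Fail against Pair-Fed for the respiratory chain (-0.95), citric acid cycle (-0.66), adipokines (0.25) and adipocyte markers (0.60), and in Success against Fail for Ndufb6 (0.0319), the respiratory chain (0.38), citric acid cycle (0.40), cell cycle (-0.23) and endothelial markers (-0.23). Matrix genes in Success against Fail were at -0.13 there (adjusted p = 0.20). With the epithelium covariate, macrophage genes in Success against Pair-Fed turned to 0.0625 and Lalba in Success against Fail to -0.0108. A covariate that differs between groups also takes up part of their difference.

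Leaving out 1 array gave fat probe set counts in limma of 0 to 22, 0 to 42 and 0 to 1116, and 0 to 202 by the F test. The highest count came without Success 1 for the first and without Fail 3 for the others. Hypothalamus counts were 1 to 65 for Success against Pair-Fed, highest without Success 2, 0 to 6 for Success against Fail, and 1 to 5 by the F test. List counts in hypothalamus were 0 to 7, 5 to 9 and 1 to 4. For the difference between tissues counts were 0 to 41, 0 to 17 and 0 to 132. Leaving out 1 array, the fat respiratory chain ran from -0.28 to 0.45 and the citric acid cycle from -0.13 to 0.63 in Fail against Pair-Fed, and the citric acid cycle from -0.64 to 0.12 in Success against Fail, with the sign turned only without Fail 2.

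With the replicate number as a replicate block, fat had 0, 0 and 0 probe sets in limma and 12, 10 and 14 lists, and hypothalamus 2, 0 and 2 probe sets and 3, 9 and 4 lists. The difference between tissues had 0 in each comparison. Residuals of arrays with the same number correlated at -0.08 to 0.30 within fat, -0.16 to 0.07 within hypothalamus and -0.06 to 0.20 between the tissues. Between the tissues 4 of 9 pairs with the same number exceeded 0.1 (median 0.06), against 1 of 18 with different numbers (median -0.02). Whether the numbers pair fat and hypothalamus of 1 animal is thus neither shown nor excluded. The main tests did not use the numbers to pair samples.

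Low signal limits the results for some genes, such as Lep and Ucp1 in fat, with signals of 8.19 to 191 and 25.6 to 223, which were not tested. Each has 1 probe set, so a weakly expressed gene cannot be told from a weak probe set.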

Other observations

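Some members of lists that camera did not call passed over their list alone and not over all probe sets. In hypothalamus of RYGB-Success against Pair-Fed, Trh, thyrotropin-releasing hormone, had a change of 1.48 ± 0.34, Vegfa, a growth factor for vessels, 0.95 ± 0.23, and the glucocorticoid targets Cdkn1a and Mt1 1.57 ± 0.43 and 1.64 ± 0.48. The choroid plexus gene Kcne2 had 1.37 ± 0.34, the astrocyte genes Gjb6 and Aldoc 0.67 ± 0.22 and 0.60 ± 0.19, the interferon gene Rsad2 1.58 ± 0.40, Rpl30 1.81 ± 0.46, at least 2.92-fold when held at the filter's signal, and Neurod2, a forebrain transcription factor, -2.14 ± 0.62. The lists of these genes had adjusted p = 0.0819 to 0.844. In RYGB-Fail against Pair-Fed fat, among thermogenic adipocyte genes, Cox8b, a subunit also made in muscle, had 4.58 ± 1.20, at least 14.2-fold with arrays held at no less than the filter's signal, beside the muscle marker shift of 5.59, and Cidea, a lipid droplet protein, -1.27 ± 0.37. In RYGB-Success against RYGB-Fail fat, the hypoxia genes Slc2a1 and Ndrg1 had 2.19 ± 0.51 and 1.25 ± 0.36, Vldlr, a lipoprotein receptor, -1.43 ± 0.38, and the smooth muscle genes Myh11 and Mylk 1.24 ± 0.30 and 1.07 ± 0.27. These list-alone results were not rerun without single arrays.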
